A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

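Total RNA of Saccharomyces cerevisiae TMB3500 was measured on Affymetrix 3′ expression arrays in 5 groups of 2 biological replicates (10 arrays), per the labels: the start of the feed, and 9 h and 18 h of a hydrolysate feed or of a sugar feed. RNA was extracted with Trizol and amplified once with biotin marking, per the labels' protocols. The array type is not given in the sources used here. The deposited log2 values are intensities after robust multi-array averaging (RMA), made with R 4.2.1, affy 1.74.0 and limma 3.52.4 per the submitters' processing notes, which state neither order nor role of the tools. The authors' deposited table also holds a log2 difference, a t score, a p-value, an adjusted p-value and a call score (1, -1 or 0) for each feed comparison. Its column headers name the adjustment and the call global. Its t score was 0 up to an absolute log2 difference of 0.9983 at 9 h and 0.9997 at the later time, and the threshold behind it is not stated. That table gives the later time as 17 h where the labels give 18 h; its log2 differences and those computed here differed by at most 9.4e-14, so the same arrays were compared.

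The value table held 10928 probe sets, of which 10925 were annotated in the authors' deposited table. Its 3 emptied lines and 10 per-array columns were not used. Of 5811 S. cerevisiae probe sets, 108 carried no gene name and 1 named several genes, and these were left out of the gene tests. The other 5702 gave 5654 genes. Where a gene had more than 1 probe set (46 genes), the one with the highest mean over all arrays was taken. For 111 genes the probe set is shared with a near-identical copy. Gene coordinates are those of the authors' deposited table, and 5585 of 5643 genes matched to the reference had the same start and end there. Background was the 95th percentile of the 5028 Schizosaccharomyces pombe probe sets on each array (4.67 to 4.9), and 5451 genes exceeded it on every array. A further 86 probe sets were controls and other sequences. The number of arrays limits the precision.

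Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior) in a single fit of all 10 arrays, with 5 residual and 3.49 prior degrees of freedom. The 9 comparisons were hydrolysate against sugar feed at 9 h and at 18 h, the difference between these, each feed and time against the start, and 18 h against 9 h in each feed. P-values were adjusted by Benjamini and Hochberg's method over all genes and called under 0.05. The 34 gene lists, each with at least 5 measured members, were tested with camera at a preset correlation of 0.01 between genes. The adjusted p of camera with an estimated correlation is given with the called lists, as a range or the lowest value of a comparison. A count "adjusted over the list alone" adjusts the same p-values over the list's members only. Sample groups, designs, lists, alternatives and the rule for named genes were chosen before the data were examined.

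Genes named for the largest changes were called, with both arrays of one group above both of the other and the brighter group above background. The 10 largest rises and falls were taken for each feed comparison, and 3 for each other comparison and for the difference between times. Up to 4 called members were named for each list described, by size of change alone, without the rule on arrays and background. In addition, 30 key genes were reported whatever their values. Of the genes the rule chose, 2 are not reported here. Fold changes of genes below background in the lower group are given as "at least".

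On simulated data with 50 genes changed at each size, the 9 h comparison recovered 10%, 80%, 96% and 100% of log2 changes of 0.5, 1, 2 and 3, with 2.05% of calls false. At 18 h these were 14%, 78%, 100% and 100%, with 6.41% false, and for the difference between times 0%, 50%, 94% and 100%, with 3.94% false. Camera recovered 60 of 60 lists shifted by 0.5 and called 4 of 573 unshifted ones over 20 simulations. Simulated genes were drawn independently of each other, with the same spread in every group. The simulations also held fewer changed genes than were called at 9 h (547), at 18 h (3502) or for the difference between times (1548). The adjusted threshold depends on that share. These rates therefore do not cover correlation between genes, unequal spread between groups or the share of changed genes in the real data.

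Alternatives were a trended and robust prior, removal of dim genes, a fit of only the arrays compared, a block of replicate numbers, a random block of feed and number, all probe sets, quantile normalization again, median centring, the mean of probe sets, a 2-fold minimum, each array left out in turn, the authors' calls, camera with an estimated correlation, and fry. With the trended prior and with both blocks, lists were tested with preranked camera (cameraPR) on the moderated t scores. Their list calls thus differ from the reported ones in the test as well as in the fit. Removal of the trend on gene length (loess, span 0.5, 5601 genes) and scaling by 9 hybridization spike-in probe sets were added after seeing the data. Gene length was the span from start to end, introns included, since no exon table was at hand.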

Results

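Transcript levels were measured in the yeast Saccharomyces cerevisiae, strain TMB3500, with single-colour Affymetrix 3′ expression arrays, which read biotin-marked RNA copied from the 3′ ends of messages. Aerobic batch cultures on glucose were followed by a fed-batch phase, in which fresh medium was added continuously. The feed was either spruce hydrolysate used without detoxification, the sugar liquor obtained from wood together with the by-products of its preparation, or a mixture of glucose, mannose and xylose at similar sugar concentrations. The 10 arrays fell into 5 groups of 2 biological replicates: the start of the feed (0 h), and 9 h and 18 h of each feed. The feed was raised from 0.04 to 0.1 L/h over 16 h, and 1 L was added to a batch of 0.7 L. All levels are the deposited log2 values after robust multi-array averaging (RMA), and 5654 named genes were tested. With 2 arrays in a group, the number of arrays limited the precision. Between 97.24% and 98.6% of genes exceeded the background level of their array, and 59 genes did so on none.

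The first principal component held 44.2% of the variance and the second 31.1%. The start and the sugar feed at 18 h lay at low values of the first component, both feeds at 9 h at high values, and the hydrolysate feed at 18 h between them. Replicates correlated across genes between 0.9706 (hydrolysate, 9 h) and 0.9956 (sugar, 18 h). Hydrolysate replicate 2 at 9 h correlated more with the sugar replicates at 9 h (0.9714 and 0.9749) than with its own replicate (0.9706). The hydrolysate replicates at 9 h differed at least 2-fold in 201 genes, against 9 genes for the sugar replicates at 18 h.

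**Figure D1:**
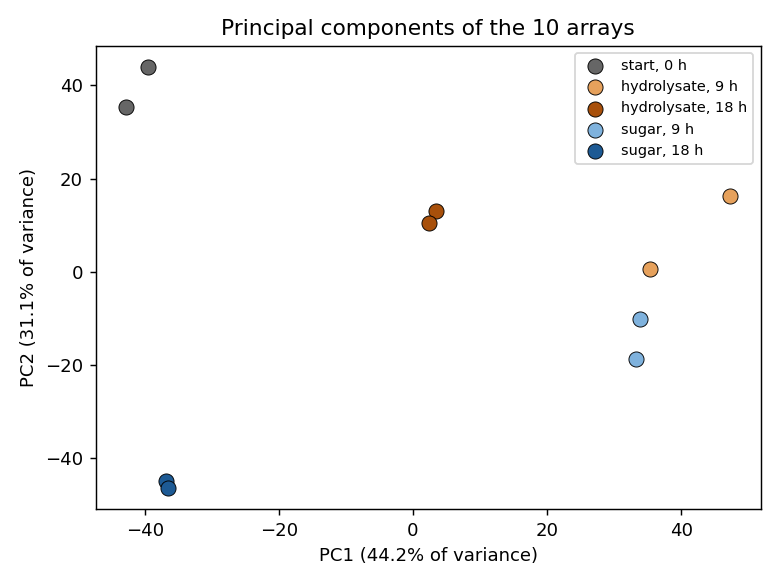
Scores of the 10 arrays on the first (x axis) and second (y axis) principal components of the log2 values, in log2 units, 1 point per array, coloured by group. The components held 44.2% and 31.1% of the variance, and hydrolysate replicate 2 at 9 h (35.38, 0.6538) lies nearer to sugar replicate 2 at 9 h (33.83, -10.19) than to its own replicate (47.3, 16.35).

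The signal of 8 control genes was read near both ends of the message. The 3′ minus 5′ difference averaged 0.96 ± 0.049 (log2, SD, n = 2) in the hydrolysate feed and 0.669 ± 0.003 in the sugar feed at 9 h, and 1.23 ± 0.052 and 0.599 ± 0.0077 at 18 h. It was larger in hydrolysate for 7 of 8 control genes at 9 h and for 8 of 8 at 18 h. The 24 ribosomal RNA probe sets averaged 6.93 and 5.93 at 9 h (hydrolysate and sugar), 7.15 and 7.52 at 18 h, and 8.12 at the start. Hybridization spike-ins, RNAs added before hybridization, averaged 11.87 at the start and between 10.64 and 10.93 in the other groups.

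**Figure D2:**
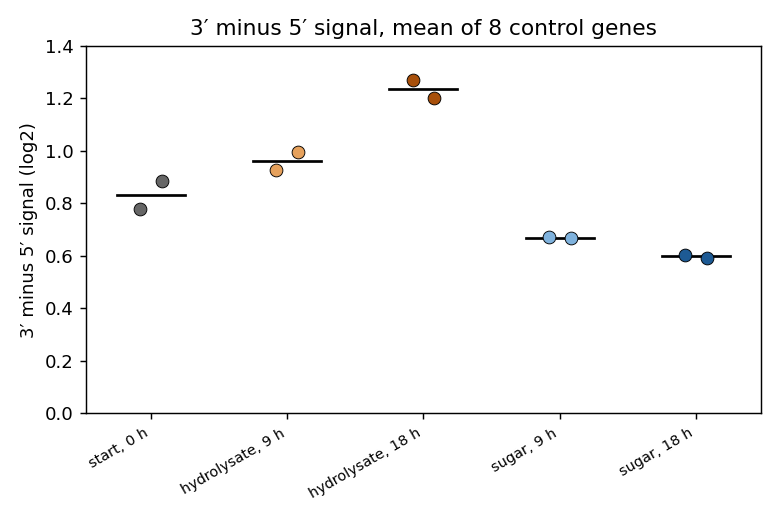
Mean 3′ minus 5′ signal of 8 control genes (y axis, log2) on each array (points) in the 5 groups (x axis), with group means as lines. The hydrolysate feed at 18 h had the highest mean, 1.23, and the sugar feed at 18 h the lowest, 0.599.

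The comparison of feeds at 9 h asked how cells growing on hydrolysate differed from cells given the sugars alone. The largest rises were in the galactose utilization genes. GAL7, the transferase of that pathway (YBR018C, chromosome II, 274427 to 275527), averaged 13.95 ± 0.0271 (log2, SD, n = 2) in hydrolysate and 6.11 ± 0.33 in the sugar feed. Its log2 difference was 7.84 (SE 0.242, limma adjusted p = 9.73e-07). GAL10 (chromosome II, 276253 to 278352) rose by 7.81, the galactose permease gene GAL2 (chromosome XII, 290212 to 291936) by 7.66 and the galactokinase gene GAL1 (chromosome II, 279021 to 280607) by 5.92. The peptide transporter gene PTR2 and the predicted transporter genes YHK8 and MCH2 rose by 3.20, 2.94 and 2.73, and AIM33 by 2.64. The small reading frames YPR159C-A and YBL008W-A, below background in the sugar feed, were at least 5.51-fold and at least 4.23-fold higher.

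Single metal and sulfate uptake genes stood among the largest falls at 9 h. Camera called none of their lists at this time, and iron uptake had more members called higher than lower. CTR1, the high-affinity copper transporter (YPR124W, chromosome XVI, 786208 to 787428), fell by 3.13 (SE 0.316, limma adjusted p = 0.00192). FET4, a low-affinity iron transporter, fell by 2.71, the zinc transporter gene ZRT1 by 2.23 and the sulfate permease gene SUL1 by 2.59. Further falls were in PDC6 (-3.10), the hexose transporter gene HXT2 (-3.04), the protein kinase gene RCK1 (-2.91), the aquaporin gene AQY1 (-2.83), HEF3 (-2.78) and SHC1 (-2.26). The metallothionein gene CUP1-1, whose probe set is shared with a near-identical copy, rose by 2.06.

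Genes linked to the handling of aldehydes and other inhibitors moved in part. In the list for aldehyde and furan reduction, 6 of 22 measured members were higher, 1 lower and 15 not called, and the same 6 and 1 counts held when adjusted over the list alone. The oxidoreductase genes AAD4 (2.55), OYE3 (2.29), AAD6 (2.29) and OYE2 (2.28) led it, and ADH6, a reductase acting on furan aldehydes, rose by 1.00. limma's camera did not call the list (adjusted p = 0.104). ADH7 (-0.39), GRE2 (0.45), GRE3 (-0.09), ARI1 (0.08), PAD1 (-0.34) and FDC1 (-0.05) were not called. Multidrug and polyamine transport had 5 members higher and 1 lower of 28 (9 and 1 adjusted over the list alone), with FLR1 at 2.59, ATR1 at 2.23, SNQ2 at 1.28 and PDR10 at -1.62, and camera called it higher (adjusted p = 0.018; adjusted p = 0.747 with an estimated correlation). PDR5 (0.20), PDR12 (0.38), YAP1 (0.07), ZWF1 (-0.24), HAA1 (0.21), TPS1 (-0.55), HSP12 (-0.10) and HSP30 (2.86; limma adjusted p = 0.0506) were not called.

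Camera called respiration, the proteasome and the tricarboxylic acid cycle higher at 9 h, each with few called members. With an estimated correlation each of these lists had an adjusted p = 0.747 and was not called. Of 40 respiratory chain and ATP synthase genes 4 were higher and none lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.000274), among them the regulator gene HAP4 (1.21) and ATP14 (0.93). Of 36 proteasome genes 7 were higher (11 adjusted over the list alone, adjusted p = 0.018), with UMP1 at 1.02 and the regulator gene RPN4 at 0.77. The tricarboxylic acid cycle had 4 of 21 members higher (6 adjusted over the list alone, adjusted p = 0.0384), with the succinate dehydrogenase genes SDH3 (0.67) and SDH4 (0.62). That call was lost with a replicate block (0.0571) and a random block (0.0533), both tested with preranked camera, and with spike-in scaling (0.112). The shortest 25% of genes had a median difference of 0.163 and the longest 25% -0.0396, and the respiratory list's median of 0.36 became 0.20 once the trend on gene length was removed, an alternative chosen after seeing the data.

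Camera called 11 lists lower at 9 h, most of them with few called members. With an estimated correlation none was called (adjusted p between 0.747 and 0.819). Peroxisomal beta-oxidation, the breakdown of fatty acids, had the largest median (-1.12) with 2 of 20 members lower (11 adjusted over the list alone, adjusted p = 0.000274), DCI1 at -1.68 and PEX18 at -1.31. The hydrolysate replicates stood apart in this list and the non-fermentable carbon list (median of replicate 1 minus replicate 2 of -1.28 over 46 genes), and without replicate 1 DCI1 was -1.12 and PEX18 -0.80. Trehalose and glycogen metabolism had 1 of 21 lower (adjusted p = 0.00324), GSY1 at -1.12. At an adjusted p = 0.018 stood the cell wall (2 of 35 lower; CWP1 -2.15, SLT2 -0.76), other amino acid synthesis (2 higher and 2 lower of 49), the cell cycle (1 and 1 of 41) and ribosomal proteins (1 of 129 lower, RPS10B at -0.72; median -0.08). Nitrogen scavenging (1 higher and 1 lower of 31; adjusted p = 0.0226), anaerobic and hypoxic genes (none lower and CYC7, at 0.75, higher of 26; 0.0263), osmotic and salt response (1 and 1 of 22; 0.0272), gluconeogenesis, glyoxylate cycle and non-fermentable carbon (2 higher and 1 lower of 27; 0.0272) and the DNA damage response (2 of 19 lower, RNR3 at -1.85; 0.0451) completed them. Adjusted over the list alone, the counts were 1 lower (trehalose), 2 lower (cell wall), 2 and 2 (other amino acids), none (cell cycle, anaerobic), 1 lower (ribosomal), 2 and 2 (nitrogen), 1 and 2 (osmotic), 2 and 5 (gluconeogenesis) and 3 lower (DNA damage). Removing the trend on gene length ended 5 of these calls, the DNA damage response (camera adjusted p = 0.0825), gluconeogenesis (0.0689), and nitrogen scavenging, osmotic response and other amino acid synthesis (0.0537).

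The remaining 19 lists, aldehyde and furan reduction and iron, zinc and copper among them, were not called at 9 h, with adjusted p between 0.104 and 0.873. Mean and test differed in sign from the median or each other for oxidative stress defence (4 of 33 higher; median 0.08, mean -0.06), weak acid response (2 of 18 higher; 0.20 and -0.12), sulfate assimilation and methionine synthesis (2 of 30 lower; 0.02 and -0.08), thiamine and pyridoxine synthesis (1 higher and 2 lower of 19; -0.02 and 0.02) and phosphate scavenging (1 and 1 of 20; 0.03 and 0.13, test downward). Iron uptake had 5 higher and 3 lower of 32, and zinc and copper homeostasis 1 higher and 4 lower of 18. Hexose transport had 2 higher and 1 lower of 22, glycolysis and alcoholic fermentation 1 and 1 of 28, ergosterol synthesis 1 and 1 of 29, the pentose phosphate pathway and xylose 1 of 16 lower (XYL2, -1.33). Heat shock chaperones (1 of 30), endoplasmic reticulum folding (1 of 20), mating types and pheromone response (1 of 22) and meiosis and sporulation (1 of 36) had 1 higher each. No member of arginine synthesis (10), ribosome biogenesis (70) or autophagy (24) was called. ADH1 rose by 0.63 and FBP1 by 0.64, and GAP1 (-1.004), MET3 (0.13), HXT1 (0.25), HXT7 (-0.13, shared probe set), PDC1 (-0.14), ADH2 (-1.94), ACS1 (-1.66) and XKS1 (0.07) were not called.

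In all, limma called 547 of 5654 genes at 9 h (9.675%), 326 higher and 221 lower in hydrolysate, and 185 of them differed at least 2-fold. This count rested on single arrays: it was 48 without hydrolysate replicate 1 and 1550 without hydrolysate replicate 2 at 9 h, 39 and 30 without sugar replicate 1 or 2 at 9 h, 293 without either hydrolysate array at 18 h and 137 without either sugar array at 18 h. Fitted on the 4 arrays compared alone it was 23. The authors' deposited table called 25 with another test, whose t score was 0 up to an absolute log2 difference of 0.9983, so the counts are not comparable. All 25 were called here too, and their direction is shared by construction, since the log2 differences are the same. Of 47 called genes named here at 9 h, 15 kept the call without each array in turn, namely GAL1, GAL2, GAL7, GAL10, YHK8, CTR1, FET4, ZRT1, CUP1-1, RCK1, AQY1, AAD4, OYE3, FLR1 and ATR1. The other 32 lost it without at least 1 array, with adjusted p up to 0.0716 for PTR2 (without sugar replicate 2 at 9 h), 0.0554 for HXT2, 0.0842 for SUL1, 0.166 for ADH6 and 0.186 for PDC6 (each without sugar replicate 1 at 9 h). Without hydrolysate replicate 1, sugar replicate 1 or sugar replicate 2 at 9 h the calls of MCH2 (up to 0.113), AIM33 (0.133), YPR159C-A (0.0931) and YBL008W-A (0.102) were lost. The adjusted p also reached 0.228 for CYC7, 0.215 for PEX18, 0.2 for ATP14, 0.195 for XYL2, 0.189 for FBP1, 0.175 for ADH1, 0.171 for PDR10, 0.165 for HEF3, 0.164 for CWP1, 0.149 for HAP4, 0.141 for DCI1, 0.14 for GSY1 and 0.137 for SDH4. It reached 0.129 for SDH3, 0.128 for AAD6 and RNR3, 0.115 for SLT2, 0.113 for RPN4, 0.112 for RPS10B, 0.109 for UMP1, 0.105 for SHC1, 0.102 for OYE2 and 0.0922 for SNQ2. Without hydrolysate replicate 1 at 9 h, 8 of these log2 values shrank most: PDC6 to -1.52, HEF3 to -1.53, XYL2 to -0.715, PDR10 to -0.95, CYC7 to 0.46, PEX18 to -0.80, GSY1 to -0.74 and DCI1 to -1.12. Camera called 7 lists without hydrolysate replicate 1 at 9 h and 9 without sugar replicate 1, and the lists for respiration and peroxisomal beta-oxidation kept the call without each array. Without hydrolysate replicate 2 the adjusted p was 0.204 for the proteasome, 0.0736 for multidrug transport, 0.312 for the tricarboxylic acid cycle and 0.232 for ribosomal proteins. Without hydrolysate replicate 1 it was 0.212 for trehalose and glycogen, 0.0749 for the cell wall, 0.157 for the cell cycle and anaerobic genes, 0.367 for osmotic response and 0.785, in the other direction, for gluconeogenesis. Nitrogen scavenging and other amino acid synthesis reached 0.0652 without hydrolysate replicate 1 and 0.0632 without replicate 2 at 9 h, and the DNA damage response 0.0936 and 0.0503. Without sugar replicate 1 at 9 h the adjusted p was 0.119 for osmotic response, 0.0916 for nitrogen scavenging and the cell cycle, 0.083 for the DNA damage response, 0.057 for gluconeogenesis and 0.0509 for anaerobic genes. Without sugar replicate 2 it was 0.0966 for the tricarboxylic acid cycle, 0.0733 for ribosomal proteins, 0.0563 for the DNA damage response and 0.0507 for gluconeogenesis, and without either array at the start 0.0562 for the last 2 lists. With a trended and robust prior and preranked camera together, 5 lists lost the call, osmotic response and the DNA damage response (0.0545), nitrogen scavenging (0.0581), gluconeogenesis and anaerobic genes (0.0598). With spike-in scaling, chosen after seeing the data, 69.5% of called genes were higher, against 59.6%.

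**Figure D3:**
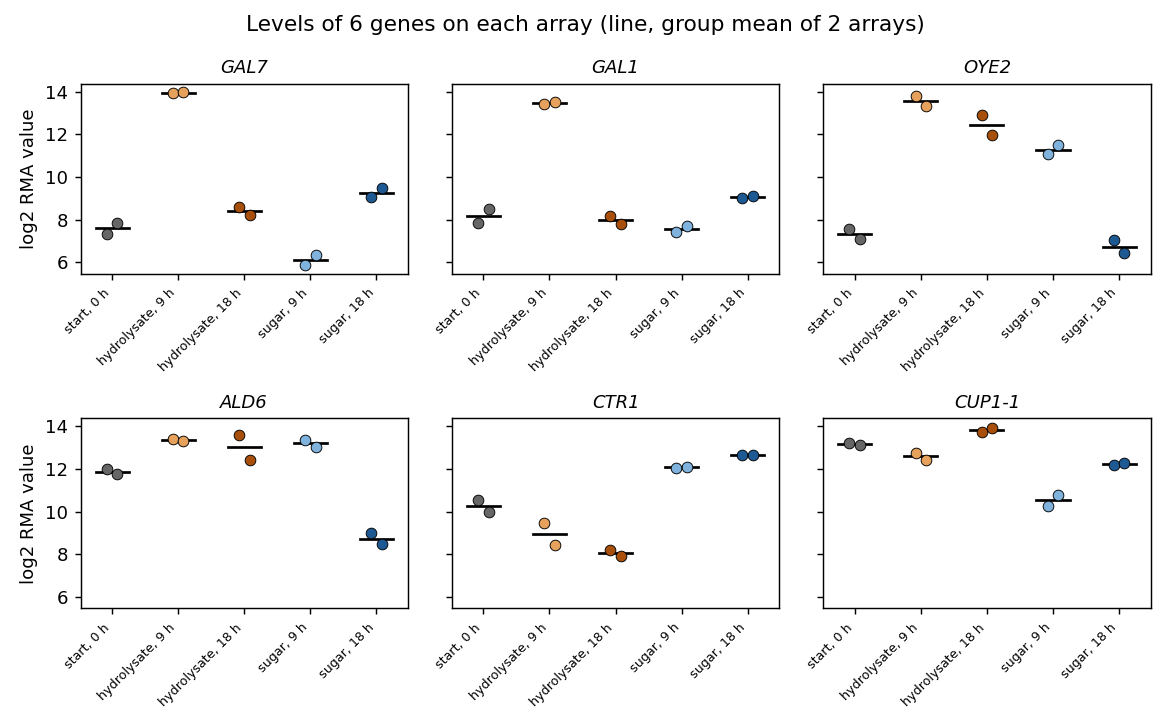
Log2 RMA values (y axis) of GAL7, GAL1, OYE2, ALD6, CTR1 and CUP1-1 on each array (points) in the 5 groups (x axis), with group means as lines. GAL7 averaged 13.95 in the hydrolysate feed at 9 h and 8.40 at 18 h, and CTR1 fell by 3.13 and 4.59 in hydrolysate against the sugar feed at 9 h and 18 h.

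The comparison of feeds at 18 h asked the same question at the end of cultivation. OYE2, an NADPH oxidoreductase gene (YHR179W, chromosome VIII, 462502 to 463704), showed the largest rise. It averaged 12.43 ± 0.64 (log2, SD, n = 2) in hydrolysate and 6.73 ± 0.44 in the sugar feed, a difference of 5.71 (SE 0.343, limma adjusted p = 2.31e-05). ALD6, the cytosolic acetaldehyde dehydrogenase gene (chromosome XVI, 432588 to 434090), rose by 4.29, and TKL1, the transketolase gene of the pentose phosphate pathway, by 4.03. YDR222W (5.12), FSH1 (4.32), YER158C (4.16), the isomaltase gene IMA1 (4.08), NRS1 (4.04), the mitochondrial carrier gene YMC2 (3.90) and DTD1 (3.88) completed the largest rises. CTR1 fell by 4.59 (SE 0.316, limma adjusted p = 4.13e-05). SPS22 (-4.00), BAG7 (-3.88), FMP48 (-3.87), RGS2 (-3.65), the methionine permease gene MUP1 (-3.58), the cell cycle inhibitor gene WHI5 (-3.42), ALT2 (-3.34), the stress regulator gene CIN5 (-3.31) and RCK1 (-3.23) also fell.

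At 18 h camera called 5 lists higher in hydrolysate, on translation, respiration and sterols, and 7 lower, among them sulfur, storage carbohydrate and cell wall genes. With an estimated correlation each of these 12 lists had an adjusted p = 0.808 and was not called. Of 129 ribosomal protein genes 96 were higher and 1 lower (98 and 1 adjusted over the list alone), with RPL41A at 3.04, RPS22A at 2.37 and RPL15A at 2.06; limma's camera gave an adjusted p = 6.71e-13. Respiratory chain and ATP synthase had 30 higher and 2 lower of 40 (30 and 3 adjusted over the list alone, adjusted p = 2.04e-05), with CYC1 at 3.60, HAP4 at 2.86 and ATP17 at 2.05. The tricarboxylic acid cycle had 13 higher and 1 lower of 21 (the same adjusted over the list alone, 0.0188), with IDP1 at 1.45. Ribosome biogenesis had 29 higher and 4 lower of 70 (26 and 2 adjusted over the list alone, 0.0188), with RRP36 at 2.23 and KRR1 at 2.19. Ergosterol synthesis, which makes the membrane sterol of yeast, had 14 higher and 4 lower of 29 (the same adjusted over the list alone, 0.0485), with ERG4 at 3.78 and ERG3 at 3.24. Beside these stood the larger 3′ minus 5′ signal difference in hydrolysate, 0.634 (log2) above the sugar feed, and a fall of the difference with gene length: the shortest 25% of genes had a median of 0.467 and the longest 25% -0.352. Removing that trend, an alternative chosen after seeing the data, took the median of the ribosomal proteins with a length from 0.88 to 0.58 and that of respiration from 0.80 to 0.34. Of the 12 called lists it ended the call of the cell cycle (camera adjusted p = 0.0941).

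Sulfate assimilation and methionine synthesis had 23 lower and 2 higher of 30 (23 and 3 adjusted over the list alone, camera adjusted p = 0.000661), with MUP1, SUL2 (-2.83) and MET17 (-2.23) lower, and SAM4 (3.61), a homocysteine methyltransferase gene, higher. The cell wall had 24 lower and 4 higher of 35 (the same adjusted over the list alone, 0.00189), with the mannoprotein genes PIR1 (-3.20) and CWP1 (-3.10). Trehalose and glycogen metabolism had 13 of 21 lower (13 adjusted over the list alone, 0.00228), with GSY1 at -2.50 and GLG2 at -1.58, and TPS1 fell by 1.19. Anaerobic and hypoxic genes had 12 lower and 3 higher of 26 (the same adjusted over the list alone, 0.0188; TIR4 -2.00, PAU7 -1.98). Peroxisomal beta-oxidation had 13 lower and 2 higher of 20 (14 and 2 adjusted over the list alone, 0.0284; SPS19 -2.26, DCI1 -2.11). Autophagy had 13 lower and 3 higher of 24 (the same adjusted over the list alone, 0.0306; ATG29 -1.80). The cell cycle had 18 lower and 4 higher of 41 (the same adjusted over the list alone, 0.0452), with the chitinase gene CTS1 at -2.70 and the replication gene MCM5 at 2.44. With a trended and robust prior and preranked camera together, 3 lists lost the call, peroxisomal beta-oxidation (0.119), ribosome biogenesis (0.0701) and autophagy (0.0629). Ribosome biogenesis lost it without sugar replicate 1 at 18 h (0.162), and the tricarboxylic acid cycle (0.0572) and peroxisomal beta-oxidation (0.0726) without hydrolysate replicate 2 at 18 h. The cell cycle (up to 0.145) lost it without hydrolysate replicate 2 or sugar replicate 1 at 18 h (0.134), either array at 0 h (0.0566) or either hydrolysate array at 9 h (0.0561). Ergosterol synthesis lost it without any array but hydrolysate replicate 2 and sugar replicate 1 at 18 h, with adjusted p from 0.055 to 0.0723.

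Lists not called at 18 h, with adjusted p between 0.0722 and 0.916, often held members moving both ways. Aldehyde and furan reduction had 7 higher and 5 lower of 22 (5 and 5 adjusted over the list alone), with OYE2, ALD6, ADH6 (2.90) and OYE3 (2.39) higher and PAD1 (-1.01) lower, while ADH7 (-0.59), GRE2 (0.02), GRE3 (-0.56) and FDC1 (-0.46) were not called. Weak acid response had 6 higher and 2 lower of 18, with PDR12, the exporter of weak acids, at 2.69, and the regulator gene HAA1 fell by 1.07. Multidrug and polyamine transport had 9 higher and 8 lower of 28 (median -0.11, mean 0.09, test downward), with PDR16 at 3.28 and PDR18 at -2.64. The pentose phosphate pathway and xylose had 4 higher and 7 lower of 16, with RKI1 at 3.18, XYL2 at -2.38 and ZWF1 at -1.74. Nitrogen scavenging (10 higher, 4 lower of 31; DAL3 3.53, MEP2 2.80), other amino acid synthesis (17 and 3 of 49; HIS1 3.24, ASN1 3.14), arginine synthesis (4 and 1 of 10; ARG1 3.66) and thiamine and pyridoxine synthesis (6 and 4 of 19; SNZ3 2.52) held large rises. Glycolysis and alcoholic fermentation had 4 higher and 12 lower of 28, with HXK2 at 2.55 and HXK1 at -2.34, and hexose transport 7 and 5 of 22. Gluconeogenesis had 7 higher and 3 lower of 27, with FBP1 at 3.51 and PCK1 at 3.19. Zinc and copper homeostasis had 5 higher and 9 lower of 18 and iron uptake 8 and 7 of 32, with the oxidase and permease genes FET3 (3.72) and FTR1 (2.62) higher. Heat shock chaperones (3 higher, 11 lower of 30; HSP82 -1.18), osmotic and salt response (2 and 10 of 22; STL1 2.70, DAK2 -2.44), oxidative stress defence (8 and 10 of 33; TRR1 1.88), proteasome (8 and 14 of 36), endoplasmic reticulum folding (7 and 3 of 20; SIL1 1.742), phosphate scavenging (4 and 6 of 20; PHM6 3.51), DNA damage response (5 and 10 of 19; RNR3 -2.93), mating types and pheromone response (5 and 8 of 22; AGA2 -1.94) and meiosis and sporulation (9 and 15 of 36; SPO20 -2.36) were not called as lists.

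limma called 3502 genes at 18 h (61.94%), 1763 higher and 1739 lower in hydrolysate, of which 1769 differed at least 2-fold. The count lay between 2654 and 3675 when 1 array was left out. The authors' deposited table gives this time as 17 h where the sample descriptions give 18 h. It called 215 of the tested genes higher and 89 lower, with another test as at 9 h, so the counts are not comparable. All of these genes were called here too, with a direction shared by construction. With spike-in scaling, an alternative chosen after seeing the data, the median of all genes lay at -0.22, and 37.6% of called genes were higher, against 50.34%. Of 81 called genes named here at 18 h, 78 kept the call without each array in turn. ARI1 (0.54; limma adjusted p = 0.0453) lost it without 5 arrays (up to 0.257 without hydrolysate replicate 2 at 18 h), YAP1 (-0.49) without 3 (up to 0.0797 without the same array) and SPS19 without 3 (up to 0.128, likewise). Without hydrolysate replicate 1 at 18 h MET17 was -1.39, MET3 -1.08 and MEP2 1.82, and without replicate 2 ARI1 was 0.34. Among further named genes MET3 (-1.80) fell and CUP1-1 (1.58) rose, and SNQ2 (-0.48), PDR5 (0.09), HSP12 (0.07), HSP30 (1.33), GAP1 (1.00), HXT1 (-0.87), HXT7 (0.12, shared probe set), PDC1 (-0.54), ADH1 (-0.17), ADH2 (-0.23), ACS1 (-0.53) and XKS1 (-0.36) were not called.

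**Figure D4:**
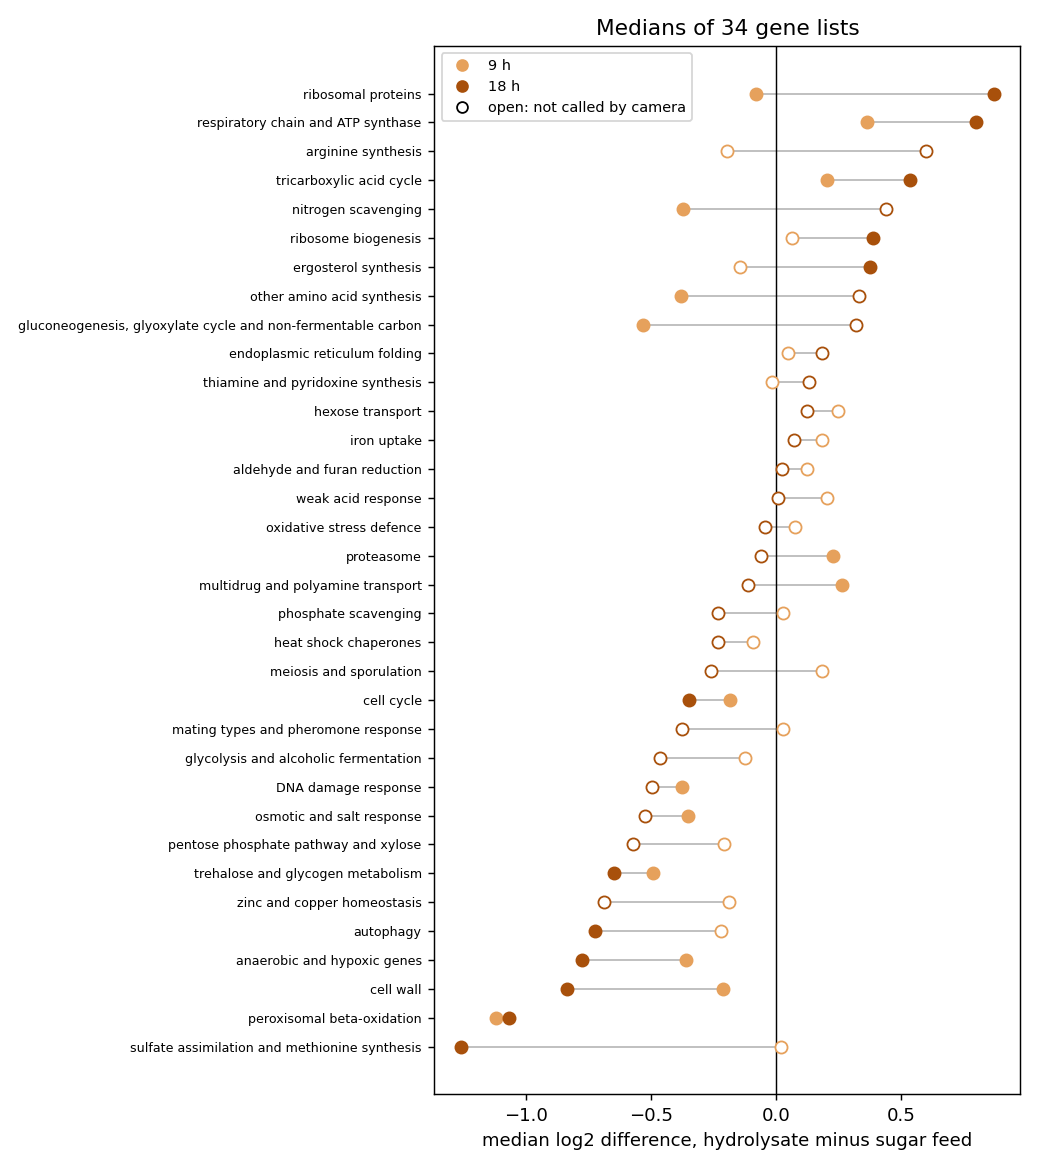
Median log2 difference between feeds (x axis) of 34 gene lists (y axis) at 9 h and 18 h, hydrolysate minus sugar feed, filled where camera called the list. The medians of ribosomal proteins were -0.08 at 9 h and 0.87 at 18 h, and those of sulfate assimilation and methionine synthesis 0.02 and -1.26.

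The feed effect was compared between the 2 times as its value at 18 h minus that at 9 h. Such a value holds the changes between the times in both feeds. It was lowest for GAL7 (-8.71, SE 0.343, limma adjusted p = 1.48e-05), GAL1 (-7.00) and GAL2 (-6.50). YDR222W (4.65), NRS1 (4.41) and ALD6 (4.13) had the highest values. Camera called 11 lists, none of them with an estimated correlation (adjusted p between 0.746 and 0.825). Of 129 ribosomal protein genes 89 had a higher feed effect at 18 h and none a lower one (98 adjusted over the list alone, camera adjusted p = 1.22e-24). Other amino acid synthesis (13 higher, 2 lower of 49; the same adjusted over the list alone, 0.000194), respiration (8 of 40; 8; 0.00114), ergosterol synthesis (12 and 2 of 29; 13 and 2; 0.00191), gluconeogenesis (6 and 1 of 27; the same, 0.00379), nitrogen scavenging (13 and 2 of 31; 14 and 2; 0.00913) and ribosome biogenesis (10 of 70; 5; 0.0121) were also called higher. Sulfate assimilation and methionine synthesis (2 higher, 14 lower of 30; 2 and 19 adjusted over the list alone, 0.000226), the cell wall (3 and 12 of 35; 3 and 15; 0.0142), the proteasome (5 of 36 lower; 4; 0.0151) and meiosis and sporulation (1 and 9 of 36; the same, 0.0459) were called lower. The 23 other lists had adjusted p between 0.0601 and 0.974, and test, median and mean differed in sign for aldehyde and furan reduction, the pentose phosphate pathway and xylose, peroxisomal beta-oxidation, iron uptake and the DNA damage response.

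limma called 1548 genes for this difference, 810 higher and 738 lower, 949 of them at least 2-fold. Among genes called in both comparisons of feeds, 239 were higher at both times (101.7 for independent lists), 173 lower at both (67.97), and 14 and 8 opposite (100.3 and 68.91). The 2 comparisons shared each gene's estimate of spread. In both, the 3′ minus 5′ signal difference was larger in hydrolysate (by 0.291 at 9 h and 0.634 at 18 h). The overlap is therefore not a measure of the feed alone. Across genes, which are not independent replicates, the log2 differences at the 2 times correlated with Pearson's r 0.555 and Spearman's rho 0.623. The count of 1548 became 653 without sugar replicate 2 at 9 h, 683 and 688 without sugar replicates 1 and 2 at 18 h, and 889 and 1011 without hydrolysate replicates 1 and 2 at 18 h. With spike-in scaling the median of all genes lay at -0.28, and 32.2% of 978 called genes were higher, against 52.33% of 1548.

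Both feeds were compared with the start. After 9 h of hydrolysate GAL7 (6.36), OYE2 (6.23) and TOS6 (5.71) rose most, and SRL4 (-6.05), BAG7 (-5.57) and RCK1 (-5.54) fell most. After 9 h of sugar feed the cyclin gene PCL1 was at least 84-fold higher, TOS6 rose by 6.76 and the ribonucleotide reductase gene RNR1 by 6.32, while YLR012C (-5.62), SRL4 (-5.35) and the gluconeogenic gene PCK1 (-5.22) fell. Camera called 13 lists in hydrolysate and 18 in the sugar feed at 9 h against the start, none of them with an estimated correlation (lowest adjusted p = 0.709 and 0.68). Ribosomal proteins (120 of 129 higher in hydrolysate, 123 in sugar feed; camera adjusted p = 5.72e-21 and 3.46e-22), ribosome biogenesis (68 and 66 of 70; 1.79e-16 and 3.65e-15), other amino acid synthesis (34 and 37 of 49; 5.73e-06 and 6.12e-07) and sulfate assimilation (24 and 25 of 30; 6.41e-05 and 2.56e-05) were called higher in both. Gluconeogenesis (22 and 16 of 27 lower; 6.41e-05 and 0.00906), peroxisomal beta-oxidation (18 and 13 of 20; 5.73e-06 and 0.0013) and meiosis and sporulation (24 and 23 of 36; 0.000114 and 5.73e-05) were called lower in both. Both comparisons used the same start arrays, so their chance values are shared. Adjusted over the list alone, ribosomal proteins had 121 and 124 higher and peroxisomal beta-oxidation 18 and 13 lower.

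At 18 h of hydrolysate the transporter gene MCH2 (5.68), OYE2 (5.11) and PTR2 (5.03) stood highest above the start, and HXT2 (-5.53), BAG7 (-5.35) and PEX9 (-4.999) lowest. At 18 h of sugar feed PTR2 (4.95), the sulfate permease gene SUL2 (4.85) and SHH3 (4.76) stood highest, and YLR012C (-5.53), YGR035C (-5.05) and PRM10 (-4.85) lowest. Camera called 9 lists in hydrolysate and 4 in the sugar feed at 18 h against the start, none of them with an estimated correlation (lowest adjusted p = 0.809 and 0.952). In hydrolysate 116 of 129 ribosomal protein genes were higher than at the start (camera adjusted p = 1.88e-17), as were 63 of 70 ribosome biogenesis genes (1.78e-12) and 12 of 19 thiamine and pyridoxine synthesis genes (0.00315; THI4 4.05). In the sugar feed 29 of 40 respiratory genes were lower (9.15e-05; CYC1 -3.59), and 22 of 30 sulfate assimilation genes (0.000271) and 43 of 70 ribosome biogenesis genes (0.000123) were higher.

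limma called 3546 genes for hydrolysate at 9 h against the start (1901 higher), 3132 at 18 h (1876 higher), 3742 for the sugar feed at 9 h (1919 higher) and 3759 at 18 h (2081 higher). Spike-in scaling, chosen after seeing the data, put the median of all genes at 1.26, 1.03, 1.21 and 1.24 in these 4 comparisons, and 95.3%, 94.9%, 94% and 92.2% of called genes were then higher, against 53.61%, 59.9%, 51.28% and 55.36%. The directions given against the start are therefore relative to the median gene of each array. Since these spike-ins were added only before hybridization, the scaled medians do not measure the amount of message in the cells.

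Between 9 h and 18 h of hydrolysate, PCK1 (5.50), SPG1 (3.86) and SHH3 (3.67) rose most, and TOS6 (-6.18), GAL10 (-5.95) and GAL7 (-5.55) fell most. In the sugar feed the membrane chaperone gene HSP30 (4.34), SPS22 (3.99) and PTR2 (3.79) rose most, and RNR1 (-6.14), TKL1 (-6.07) and TOS6 (-5.67) fell most. Camera called 14 lists in hydrolysate and 13 in the sugar feed, none with an estimated correlation (lowest adjusted p = 0.557 and 0.562). Ribosomal proteins fell in the sugar feed in 128 of 129 genes (128 adjusted over the list alone, camera adjusted p = 8.63e-29; median -1.15) and in hydrolysate in 41, with 1 higher (41 and 1; 7.47e-08; median -0.28). Autophagy genes rose in 21 of 24 in the sugar feed (21; 4.91e-06) and 15 of 24 in hydrolysate (17; 3.27e-06). Cell cycle genes fell in 27 of 41 in hydrolysate (29, with 1 higher; 4.32e-11; PCL1 -4.87) and in 21, with 6 higher, in the sugar feed (the same, 0.000854; PCL1 -5.41). Sulfate assimilation fell in 22 of 30 genes in hydrolysate, with 2 higher (22 and 3; 1e-06; CYS3 -4.04), and gluconeogenesis rose in 13 of 27, with 2 lower (15 and 2; 0.000263). Respiration fell in 17 of 40 in the sugar feed, with 2 higher (16 and 2; 0.00332; CYC1 -3.04).

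limma called 1989 genes between the times in hydrolysate (1020 higher) and 3332 in the sugar feed (1806 higher). The hydrolysate count was 1122 and 1163 without hydrolysate replicates 1 and 2 at 18 h, and 1216 when only the arrays compared were fitted. With spike-in scaling the median of all genes in hydrolysate lay at -0.23 and 16.3% of called genes were higher, against 51.28%.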

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

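Of the 8 tests of explanations in this part, 6 were chosen after the result was seen, and those on gene length and on states of glucose repression were written before their values.

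A difference between the 2 times in the effect of the feed drew attention to 1548 genes, by a limma test of that difference itself. Among lists, camera called 11, none of them with an estimated correlation (adjusted p from 0.746 to 0.825), and its adjusted p was 1.22e-24 for ribosomal proteins, 0.000194 for other amino acid synthesis, 0.000226 for sulfate assimilation and methionine synthesis, 0.00114 for the respiratory chain and ATP synthase, 0.00191 for ergosterol synthesis and 0.00379 for gluconeogenesis, glyoxylate cycle and non-fermentable carbon. It was 0.00913 for nitrogen scavenging, 0.0121 for ribosome biogenesis, 0.0142 for the cell wall, 0.0151 for the proteasome and 0.0459 for meiosis and sporulation. The named genes with a higher feed effect (log2) at 18 h than at 9 h began with YDR222W (4.65), NRS1 (4.41), ALD6 (4.13), YMC2 (3.99), TKL1 (3.96), YER158C (3.86), DTD1 (3.57), OYE2 (3.43), SAM4 (3.36), RPL41A (3.26), ERG4 (3.13), CYC1 (2.97), ERG3 (2.9) and FBP1 (2.87). Next came IMA1 (2.78), AQY1 (2.77), RPS22A (2.48), PDR12 (2.31), PCK1 (2.29), MCM5 (2.27), FSH1 (2.07), RPL15A (2.04), STL1 (2.01), GAP1 (2), ADH6 (1.91), RPS26B (1.91) and NDE1 (1.82). The smallest such differences were in PEX21 (1.81), ERG26 (1.8), BRX1 (1.73), ATP17 (1.67), IDP1 (1.65), HAP4 (1.65), DAL4 (1.61), ERG27 (1.53), KRR1 (1.5), RPS10B (1.33), HIS6 (1.29), CTP1 (0.83) and FUM1 (0.666). A lower feed effect at 18 h was seen in ADH1 (-0.807), ARO7 (-0.823), TPS2 (-0.94), ATG29 (-1.14), PAU2 (-1.23), HAA1 (-1.28), GLG2 (-1.31), FLR1 (-1.32), PAU7 (-1.36), GSY1 (-1.38), TIR2 (-1.43) and CTR1 (-1.46). Larger falls were in CIS3 (-1.49), ZWF1 (-1.5), SNQ2 (-1.76), PCL9 (-1.83), MET17 (-2.19), NCW2 (-2.2), DSE2 (-2.23), FMP48 (-2.28), CTS1 (-2.3), PIR1 (-2.35) and RGS2 (-2.92). The largest were in BAG7 (-2.98), PTR2 (-3.12), SUL2 (-3.23), WHI5 (-3.47), CIN5 (-3.47), SPS22 (-3.48), MUP1 (-3.81), GAL10 (-6.32), GAL2 (-6.5), GAL1 (-7) and GAL7 (-8.71). Of these 74 genes, 49 kept the call without each array in turn. The value itself moved most in 7, to -2.07 for WHI5 without sugar replicate 2 at 9 h, -0.934 for CTR1 without hydrolysate replicate 1 at 9 h, -1.39 for FMP48 and -0.619 for TPS2 without replicate 2 at 9 h, and 1.26 for GAP1, 1.06 for DAL4 and -1.35 for MET17 without replicate 1 at 18 h. The call was lost without 8 of the 10 arrays by FMP48 (adjusted p up to 0.148), GAP1 (0.132) and TIR2 (0.132), without 7 by ARO7 (0.14), TPS2 (0.13) and WHI5 (0.112), and without 6 by CTR1 (0.118), HAA1 (0.11), FSH1 (0.104), FUM1 (0.0988), DAL4 (0.0982), FLR1 (0.093), MET17 (0.0924) and PAU2 (0.0854). ADH1 lost it without 5 (0.0871), ATG29 (0.0758), CIS3 (0.0727) and CTP1 (0.0688) without 4, KRR1 (0.0774), GSY1 (0.0606) and GLG2 (0.0535) without 3, and SUL2 (0.0641) without 2. Without a single array it was lost by HAP4 (0.0521) and PDR12 (0.0505), in both cases sugar replicate 2 at 18 h, and by BRX1 (0.0508), for sugar replicate 2 at 9 h.

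Signal in data that no comparison used also drew attention. Of 108 S. cerevisiae probe sets without a gene name, limma called 37 at 18 h and 16 at 9 h. These probe sets were left out of the gene tests and of their adjustment. Their calls therefore rest on another threshold, and their shares cannot be compared with those of the named genes. The hybridization spike-ins were 1.13 (log2) brighter at the start than on the other arrays.

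The first pattern weighed was the higher level of ribosomal protein genes in hydrolysate at 18 h. Stronger loss of 5′ signal in hydrolysate RNA, acting through gene length, was 1 candidate explanation, and with the length trend removed the median of 112 genes went from 0.882 to 0.577 (SE 0.0582; camera adjusted p = 5.55e-07), which met the prediction written in advance for its not being the cause, though camera called this list only at the preset correlation (adjusted p = 0.808 before the correction at an estimated 0.461). That correction could be too weak for this list, since lengths included introns (41.1% of ribosomal protein spans were no multiple of 3, against 2.02% of others), so a bound was chosen afterwards: the median of the whole list exceeded the highest length trend of other genes, 0.616, by 0.254 (SE 0.106). Both SEs came from drawing genes again, as if independent, on the same arrays, so they do not cover variation between cultures. The bound, above 0 by more than 2 such SE, argues for these arrays only against gene length as the whole cause. A part of the difference up to that trend stays open. The median change from 9 h to 18 h was -1.15 in the sugar feed and -0.279 in hydrolysate, but the difference of -0.872 restates the feed differences at the 2 times and decides nothing, so an effect of the feed stays open as untested.

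The second pattern was the higher level of GAL genes in hydrolysate at 9 h. Loss of glucose repression alone might raise them, but the list of gluconeogenesis, glyoxylate cycle and non-fermentable carbon genes had a median of -0.534, against that prediction, although this list's direction turned when hydrolysate replicate 1 at 9 h was left out. The respiratory chain (median 0.364) and tricarboxylic acid cycle (0.202) lists, also glucose-repressed, were called higher by camera at the preset correlation. The lists thus went both ways and do not settle this explanation. An effect on the whole regulon, as galactose would give, stays open: 6 of 6 of GAL1, GAL2, GAL3, GAL7, GAL10 and GAL80 were called higher, but all of them except GAL3 and GAL80 are the pattern itself, and those were chosen after their values were seen, so the count decides nothing. Galactose is not mentioned in the sample descriptions, and its level was not measured here.

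The third pattern was the gap between the hydrolysate replicates at 9 h in 46 peroxisomal and non-fermentable carbon genes, with a median of replicate 1 minus replicate 2 of -1.28 (percentile 0 of 10000 random sets). These lists were picked for this gap, so the percentile only restates it. Against more degraded RNA in replicate 1, its 3′ minus 5′ signal exceeded that of replicate 2 by at most 0.019 over 3 control genes and, with the probe sets of the 8 control genes in the report, by at most 0.12 (larger in 5, beyond the gaps of other groups in 0, mean -0.069), and the median stayed at -1.27 once the trend of the gap on gene length (Spearman's rho -0.25) was removed. A sugar culture in place of replicate 2 is unlikely, since replicate 2 lay at least 5.85 above the sugar arrays in 4 GAL genes. Replicate 2 correlated more with a sugar array at 9 h (0.9749) than with its own replicate (0.9706), as a mixture with such a culture would, but in these GAL genes it lay between 0.145 below and 0.204 above replicate 1. The largest replicate gap of these genes in other groups was 0.791. Allowing for it, and taking signal as proportional to RNA, at most 47.7% of its RNA could have come from a sugar culture. That share would give the 46 genes a median of -0.86. It misses the observed median by 0.419 (SE 0.208), narrowly more than 2 SE, which met the prediction against a mixture. The SE came from drawing these genes again, as if independent, on 1 pair of arrays, so it does not cover variation between arrays. Proportional signal was not checked for genes this bright. The test therefore does not decide, and a mixture stays open. Different states of glucose repression predicted lower tricarboxylic acid cycle and respiratory genes in replicate 1 too. Their median was 0.21, at percentile 100 of random sets, against that prediction. Singly, the tricarboxylic acid cycle list gave 0.14 (percentile 98.64) and the respiratory list 0.279 (percentile 100). The random sets were matched on mean level, not on gene length or correlation between genes. The gap fell with gene length, and the respiratory genes were short (median 429 nt), so the test does not settle this explanation.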

How the results depend on the processing

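Same-numbered arrays shared little deviation from their group means, with correlations between -0.2 and 0.13 over 10 pairs of groups. This does not show whether they came from the same culture. With a replicate block the count of genes at 9 h went from 547 to 337. A random block of feed and number left it at 539, and at 3494 at 18 h. The lists of both blocks were tested with preranked camera, so their lost calls cannot be credited to the block alone. The replicate block with that test gave 7 lists at 18 h, against 12. With both blocks the lost calls at 18 h were ribosome biogenesis (0.0797 and 0.0708), peroxisomal beta-oxidation (0.112 and 0.129), autophagy (0.0678 and 0.0656), the cell cycle and the tricarboxylic acid cycle (0.0763 and 0.065). The tricarboxylic acid cycle at 9 h was lost with the replicate block (0.0571). The random block gave 9 and 7 lists at 9 h and 18 h. Lost at 9 h were the tricarboxylic acid cycle, the DNA damage response and anaerobic genes (0.0533), gluconeogenesis, nitrogen scavenging and osmotic response (0.0574) and other amino acid synthesis (0.0516). Fitting only the arrays compared gave 23 genes at 9 h and 1216 between times in hydrolysate, with fewer arrays to estimate the spread. It gave fewer against the start as well, but more at 18 h (4014), for the difference between times (1796) and between times in sugar feed (3934). Fewer arrays alone therefore do not explain the falls. The single fit pools the spread, but the SD of the replicate difference was 0.491 for hydrolysate at 9 h and 0.198 for sugar feed at 18 h. Fitting only the arrays compared ended the lists for the tricarboxylic acid cycle (0.0518), the DNA damage response (0.0504) and gluconeogenesis (0.0528) at 9 h. At 18 h it ended those for the cell cycle (0.0851) and ergosterol synthesis (0.0989). The authors' deposited calls, made with another test, numbered 25 and 304. A 2-fold minimum, which only removes calls, left 185 genes at 9 h, 1769 at 18 h, 949 for the difference between times, 1890 and 1453 for hydrolysate at 9 h and 18 h against the start, 2117 and 2010 for the sugar feed, and 665 and 1697 between times in hydrolysate and sugar feed. Estimated correlations left 0 lists at 9 h and 0 at 18 h. Fry asks another question, since it tests a list against no change, where camera tests it against the other genes. Fry called 5 lists at 9 h, only 3 of them among the 15. It did not call respiration and the DNA damage response (0.151), peroxisomal beta-oxidation (0.264), gluconeogenesis (0.41), ribosomal proteins (0.44) and other amino acid synthesis (0.486). Nor did it call anaerobic genes, the cell cycle, the cell wall, nitrogen scavenging, osmotic response and trehalose and glycogen (0.301). At 18 h it called 14, of them 10 among the 12, without peroxisomal beta-oxidation (0.0961) and ribosome biogenesis (0.109). Spike-in scaling ended the tricarboxylic acid cycle at 9 h (0.112) and ergosterol synthesis at 18 h (0.0539), and median centring the DNA damage response at 9 h (0.0551) and ergosterol synthesis at 18 h (0.0524). Quantile normalization again ended the DNA damage response (0.0601) and gluconeogenesis (0.0531) at 9 h. Spike-in scaling, chosen after seeing the data, gave 226 genes at 9 h and 978 for the difference between times. With 1 array left out, where the lone array of a group was assumed to vary like the other groups, counts ran from 30 to 1550 (9 h), 2654 to 3675 (18 h), 653 to 1889 (difference between times), 3251 to 3429 and 2387 to 3334 (hydrolysate at 9 h and 18 h against the start), 3063 to 3906 and 2953 to 3883 (sugar feed), 1122 to 2245 and 2530 to 3537 (between times in hydrolysate and sugar feed), and 7 to 15 and 10 to 13 lists (9 h and 18 h). The adjusted p of gluconeogenesis, glyoxylate cycle and non-fermentable carbon at 9 h ran from 1.78e-08 to 0.785, with the direction turned at the latter. In the comparisons of feeds, the other named values whose direction turned were not called in the reported fit. Among all genes called there and in the other comparisons, the direction turned for 1 at 9 h and 46 at 18 h with the length trend removed, for 3 at 18 h with quantile normalization again, and for 1107, 630, 1132 and 921 with spike-in scaling in the 4 comparisons with the start (hydrolysate at 9 h and 18 h, sugar feed at 9 h and 18 h). Length removal turned 16, 2, 51 and 227 in those 4 and 10 between times in the sugar feed, quantile normalization 15, 5 and 23 in the first 3, and the mean of probe sets at most 3. At 9 h, leave-one-out values ran from -0.472 to 0.285 (GRE3), -0.137 to 0.305 (ARI1), -0.308 to 0.205 (FDC1), -0.003 to 0.151 (YAP1), -0.0183 to 0.424 (PDR5), -0.018 to 0.443 (HAA1), -0.239 to 0.0352 (HSP12), -0.0605 to 0.318 (MET3) and -0.262 to 0.012 (HXT7). At 18 h they ran from -0.0162 to 0.0588 (GRE2), -0.0877 to 0.264 (PDR5), -0.183 to 0.431 (HXT7) and -0.468 to 0.00183 (ADH2), and for the difference between times from -0.53 to 0.127 (ADH7), -0.142 to 0.34 (OYE3), -0.336 to 0.107 (PDR5) and -0.0574 to 0.556 (HXT7). GRE2 at 18 h turned to -0.0147 with quantile normalization again and -0.00574 with median centring, and HXT1 at 9 h to -0.166 with the former. With the length trend removed, also chosen after seeing the data, GRE2 at 18 h was -0.0633, HSP12 -0.488 (adjusted p = 0.0329) at 18 h and -0.163 for the difference between times, and PDR5 0.333 for that difference. With spike-in scaling GRE2 was -0.206, PDR5 -0.139, HSP12 -0.16 and HXT7 -0.104 at 18 h, and OYE3 -0.134 and HSP12 -0.0632 for the difference between times. Except where the construction of an alternative shows it, the cause was not tested.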

Other observations

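The genes in this part, other than CTR1, FET4, ZRT1, FET3, FTR1 and CUP1-1, were chosen after their values were seen, and no test of an explanation was made for them. The metal genes are given singly, since camera called neither zinc and copper homeostasis (adjusted p = 0.202 at 9 h and 0.211 at 18 h; fry gave 0.0257 and 0.00135) nor iron uptake (0.373 and 0.797), and both lists had members moving both ways. The second high-affinity copper transporter gene CTR3 fell by 1.83 at 9 h and 1.64 at 18 h (log2; limma adjusted p = 0.0124 and 0.000818), beside CTR1, and FRE1, a reductase gene of copper and iron uptake, fell by 1.41 and 1.24 (0.013 and 0.000932). CUP1-1, the copper-binding metallothionein gene, was higher at both times, while the other metallothionein gene CRS5 (0.26 and -0.33; 0.41 and 0.191) and CCC2 (0.30 and 0.05; 0.315 and 0.823), which delivers copper to the iron oxidase, were not called. The low-affinity iron transporter gene FET4 fell at both times (by 2.71 at 9 h; limma adjusted p = 0.00294 at 18 h), as did the zinc transporter gene ZRT1 (by 2.23 and 1.61). FET3, the iron oxidase gene, rose by 1.46 and 3.72 (0.0256 and 6.89e-05), its partner permease gene FTR1 by 0.71 and 2.62 (0.0482 and 4.53e-05) and the siderophore transporter gene ARN1 by 2.08 and 1.30 (0.00226 and 0.00107). Without at least 1 array the 9 h calls of CTR3 and FRE1 (adjusted p up to 0.082), FET3 (0.134) and FTR1 (0.217) were lost.

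Beyond the structural genes, the galactose regulators were higher in hydrolysate at 9 h, GAL3 by 1.68 (limma adjusted p = 0.00192) and GAL80 by 1.15 (0.0155). At 18 h GAL80 was 0.60 lower (0.0153) and GAL3 not called (-0.37; 0.0843). The structural genes split at 18 h, with GAL10 (1.49; 0.000885) and GAL2 (1.16; 0.00639) higher and GAL1 (-1.08; 0.00338) and GAL7 (-0.87; 0.0131) lower in hydrolysate. Without at least 1 array the calls of GAL80 at 9 h (up to 0.0925) and 18 h (0.0923) and of GAL7 at 18 h (0.099) were lost.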
